A study of Mus musculus with 16 samples.

How the data were processed

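Mouse gene expression was measured on 16 single-channel Affymetrix arrays of 7 groups: haematopoietic stem cells (HSC) sorted from young and aged steady-state mice, HSC sorted from recipients of young and aged marrow, induced pluripotent stem cells (iPSC) of young and aged haematopoietic origin, and commercial embryonic stem cells (ESC). Per the labels, total RNA was extracted with the QIAGEN microRNeasy kit and biotinylated cRNA was prepared by the standard Affymetrix protocol. The values used were the intensity values that the authors deposited as one table of 45101 probe sets by 16 arrays. The method by which the authors summarised and normalised these intensities is not given in the sources used here. The intensities were on a linear scale, from 4.53 to 31493, with 0 missing values, and were not below 0 on any array.

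Each deposited intensity was put on the log2 scale without a pseudocount, and the authors' scaling between arrays was kept. Groups and replicate numbers came from the sample labels, and each column of the table was matched to its sample by identifier. A probe table named the genes: 34945 non-control probe sets had exactly 1 gene symbol, 932 had several and 9160 were not listed. Gene identifiers were checked against a RefSeq gene table, where 18032 of 18193 genes matched and 0 symbols changed. Each gene was represented by the probe set with the highest mean over the 16 arrays, and 9010 genes had more than 1 probe set. The 64 control probe sets were kept out of all tests and examined separately. The table held no detection calls, so a level near the array background could not be separated from absence. For arrays, the number of arrays per group, 3 or 2, limits the precision.

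Comparisons were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. The 10 HSC arrays were fitted together, the 6 iPSC and ESC arrays together, and contrasts between HSC and iPSC on all 16 arrays, with 6, 3 and 9 residual degrees of freedom. Genes below the 25th percentile of mean log2 intensity in a fit were left out, which left 13645 genes per fit. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p printed for a gene is from limma. The contrasts were aged minus young in steady-state HSC, in transplanted HSC, and averaged over both; the difference between those age effects; transplanted minus steady-state HSC; aged-origin minus young-origin iPSC; iPSC minus ESC; iPSC minus steady-state HSC; and the difference between the age effects of iPSC and steady-state HSC.

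A signature was formed from the 100 genes with the highest and the 100 with the lowest moderated t of the steady-state age contrast. Its median log2 fold change, signed by the steady-state direction, was taken in transplanted HSC and in iPSC and tested with limma's fry, whose p-value asks whether the genes move on balance one way. There were 21 gene lists, covering genes reported higher in aged HSC, HSC identity, megakaryocyte and platelet, lymphoid priming, myeloid, erythroid, mature blood, pluripotency, germ layer, fibroblast and feeder, imprinted, cell cycle, chromatin regulators, DNA damage and senescence, interferon, inflammation, immediate early, proteostasis, oxidative phosphorylation, ribosome and sex-linked genes. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast, and again with the correlation estimated from each list.

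The genes named in the text followed a rule. It took up to 10 called genes per direction with the largest change whose arrays did not overlap between the groups, up to 4 members of each list with the smallest p, and a set of identity genes; where fewer than 5 genes were called, it took the 5 with the smallest p. Groups, contrasts, lists, the naming rule and the alternatives named next were written before the data were examined. These alternatives were quantile normalisation, centring each array on its median, no filter on dim genes or a filter at the 50th percentile, the mean of a gene's probe sets, an intensity trend with a robust prior, all 16 arrays in one fit, the replicate number as a block, a required 2-fold change, pseudocounts of 1 and 64, other signature sizes, and each array left out in turn. Chosen after seeing the data were fits on the steady-state or transplanted arrays alone, array quality weights, the removal of X and Y genes, a crossed pairing of the transplanted arrays, the other scalings for the gene lists, the count of shared age calls, the comparison of called genes with the 25th percentile of their group, and the Benjamini-Hochberg adjustment of the fry p over transplanted HSC and iPSC.

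The fits were tested on 10 simulated sets of arrays with 200 changed genes per contrast. The size of the scatter in each setting followed the real arrays, but it was drawn independently for each gene. For the steady-state age contrast, 52.3% of 2-fold and 96.9% of 4-fold changes were recovered among 13645 genes, and 0.289% of the calls were false. For the transplanted age contrast, 43.9% and 92.1% were recovered and 53.1% of the calls were false, because the scatter shared with the steady-state arrays was smaller than that of the transplanted arrays. With the 4 transplanted arrays alone, 0% and 1.24% were recovered. For the age-of-origin contrast in iPSC, 96.1% and 99.7% were recovered and 7.35% of the calls were false. The signature's median over truly changed genes came out at 0.76 against a true 0.75 in simulated transplanted HSC. Its p fell under 0.05 in 2 of the 10 simulated iPSC sets that held no effect. Camera passed 0.05 for a changed list in 10 and for an unchanged list in 1 of the 10 sets. Genes of the real lists were correlated, with an estimate of 0.376 for cell cycle genes in the HSC fit. The simulated rates of camera and fry therefore do not give their error on the real lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.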

Results

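The series compared mouse HSC of young and aged animals in 3 settings: freshly sorted from steady-state marrow, sorted after transplantation of young or aged marrow into recipients, and in iPSC of young and aged haematopoietic origin, with ESC as a pluripotent reference. There were 3 arrays each of young (3 to 4 months) and aged (21 to 24 months) steady-state HSC from male mice, and 2 arrays each of young and aged transplanted HSC, young-origin and aged-origin iPSC, and ESC. All were on a C57Bl6 background, and the labels call the arrays of a group biological replicates, except the ESC, which came from 2 suppliers. The p-values measure the spread between these arrays. Median intensity ranged from 43.52 to 51.94 per array.

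The first principal component held 63.5% of the variance and separated HSC from iPSC and ESC, and the next held 26.9% and separated transplanted from steady-state HSC. Steady-state replicates correlated across genes at 0.99 or above, the young transplanted pair at 0.952 and the aged transplanted pair at 0.971; genes are not independent replicates. The median within-group SD was 0.175 log2 in steady-state HSC, 0.354 in transplanted HSC, 0.128 in iPSC and 0.102 in ESC.

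**Figure D1:**
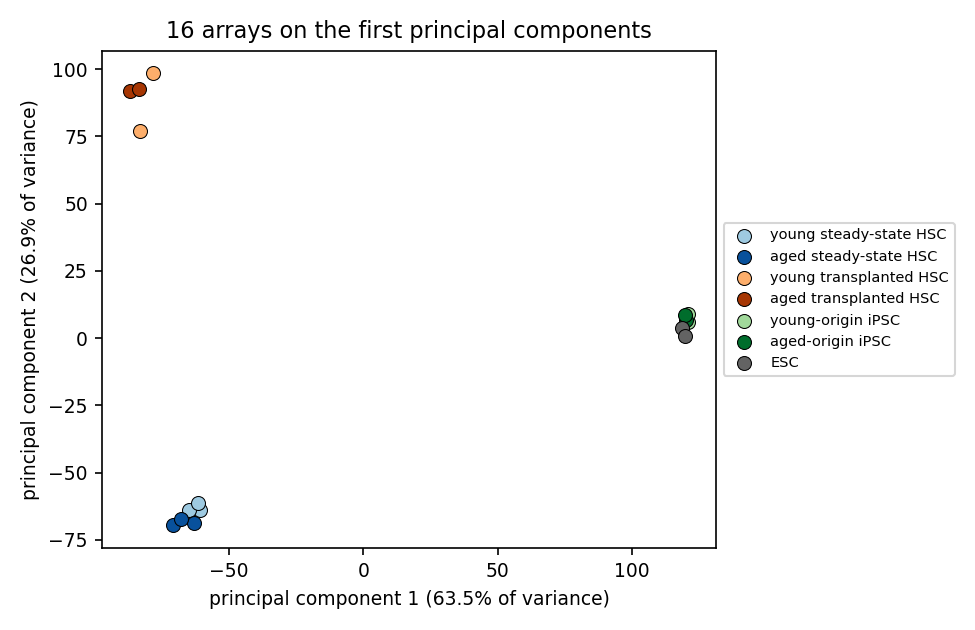
The 16 arrays on the first principal component (63.5% of the variance) and the next (26.9%), 1 point per array, coloured by group. The transplanted arrays lie apart from the steady-state HSC arrays along the vertical axis.

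Whether ageing changed steady-state HSC was asked with 3 aged against 3 young arrays. Sbspon, which encodes a secreted thrombospondin-domain protein, rose 38.7-fold (log2 5.27, SE 0.45, adjusted p = 0.000356). Osmr, the oncostatin M receptor, rose 23.6-fold (SE 0.2, adjusted p = 7.84e-06), from 4.17 ± 0.12 to 8.73 ± 0.33 log2 (SD, n = 3 each). The phospholipid scramblase gene Plscr2 rose 17.4-fold, the oxysterol receptor gene Gpr183 rose 15.1-fold and Wwtr1, which encodes the Hippo-pathway coactivator TAZ, rose 14.7-fold. Further rises were in Tc2n (13.1-fold), Tdrd9 (11.8-fold), Tm4sf1 (11.4-fold), the stress-response gene Nupr1 (10.7-fold) and Selp, the gene of the adhesion receptor P-selectin (10.2-fold). Sbspon (4.08 ± 0.87 log2), Osmr, Gpr183 and Tc2n lay below the 25th percentile of all genes (4.57) in young arrays, so the size of their folds and their rank are uncertain.

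Rgs7bp, a partner of G-protein regulators, decreased by 2.81 log2 (SE 0.21, adjusted p = 0.000149). The uncharacterised X-linked gene 6030498E09Rik fell (log2 -2.22), as did the scavenger receptor gene Cd163 (-2.18), the poly(A) polymerase gene Tent5a (-2.09) and Plac8 (-2.02), known from myeloid and lymphoid progenitors. Satb1, a chromatin organiser of lymphoid differentiation, fell by 1.92, as did the kinase gene Camk1d, while Rnase6 fell by 1.82, the nucleotide-sugar receptor gene P2ry14 by 1.80 and the cytokine subunit gene Ebi3 by 1.79. Rgs7bp, 6030498E09Rik, Cd163 and Cd48 lay below the 25th percentile in aged arrays, which leaves the size of their falls uncertain. In total 131 genes rose and 30 fell among 13645 tested, and all 161 had no overlap between the 3 aged and 3 young arrays. Of the 71 called genes with another probe set above the dim filter, 11 had at least 1 that pointed the opposite way. Over all genes 18.2% did not overlap, where chance gives 10%.

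Of the 30 listed genes that HSC studies had reported higher with age, 25 rose and 0 fell, and 30 rose when adjusted over the list alone. Their median was 2.06 log2 (camera adjusted p = 1.35e-88). Such studies may share arrays with this series, so the list is not independent evidence of its direction. Among 22 megakaryocyte and platelet genes, 5 rose and 1 fell (7 and 2 adjusted over the list alone, camera adjusted p = 2.72e-05). Vwf, Clu, Cavin2, Selp and Itgb3 were on this list and on the one reported higher with age, so these lists are not independent. The clotting glycoprotein gene Vwf rose 4.28-fold (SE 0.25 log2), Clu, which encodes a secreted chaperone, rose 7.42-fold (SE 0.40) and the caveolar gene Cavin2 rose 4.38-fold (SE 0.18), whereas the erythroid and megakaryocytic regulator Gata1 fell by 1.14 log2 (SE 0.22).

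Both of those lists kept an adjusted p under 0.05 with an estimated correlation (9.29e-06 and 0.0246). No cell cycle gene was called by limma, and 0 of 27 passed when adjusted over the list alone, but 26 of 27 lay below 0 with a median of -0.49 log2 (camera adjusted p = 5.37e-10; adjusted p = 0.219 with an estimated correlation). Interferon genes had a median of -0.38 and 0 of 19 called (camera adjusted p = 0.000615; adjusted p = 0.219 with an estimated correlation). Among 15 lymphoid priming genes, Satb1 was called, and 3 fell adjusted over the list alone (median -0.12, adjusted p = 0.0245; adjusted p = 0.219 with an estimated correlation). Fibroblast and chromatin regulator genes also stood lower (medians -0.13 each, adjusted p = 0.0245 each; adjusted p = 0.193 with an estimated correlation). The fibroblast-list gene Mmp2, a matrix protease, fell by 1.78 log2. HSC identity genes stood slightly higher (median 0.13, adjusted p = 0.0322; adjusted p = 0.574 with an estimated correlation).

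Within the identity list, Cd48, which marks cells outside the most primitive HSC gate, fell by 1.35 log2 (SE 0.21, adjusted p = 0.0133). The identity genes Kit, encoding the stem cell factor receptor (log2 0.09, SE 0.16, adjusted p = 1), Procr (0.67, adjusted p = 0.216) and Slamf1 (0.89, adjusted p = 0.186) did not pass. Flt3, a receptor of early multipotent progenitors, had a log2 fold change of -1.16 (SE 0.25) with an adjusted p of 0.0717. The neutrophil protease gene Prtn3 rose by 0.85 log2 and the imprinted gene Phlda2 fell by 1.01. The remaining lists, which were myeloid, erythroid, mature blood, pluripotency, germ layer, imprinted, DNA damage, inflammation, immediate early, proteostasis, oxidative phosphorylation, ribosome and sex-linked genes, had camera adjusted p of 0.076 or above. Leaving out any 1 of the 6 steady-state arrays gave 78 to 87 calls, and leaving out young transplanted array 1 or 2 gave 255 or 257. A fit on the 6 steady-state arrays alone gave 415 calls, which held all 161.

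The persistence of age differences after transplantation was asked with 2 aged against 2 young arrays. Plscr2 rose 8.61-fold (SE 0.26 log2, adjusted p = 0.00157), from 5.61 ± 0.31 to 8.72 ± 0.16 log2 (SD, n = 2 each). Igk, the immunoglobulin kappa light chain, rose 23.7-fold (SE 0.43, adjusted p = 0.00279) and its variable segment Igkv8-30 rose 11.9-fold. Tmem254a rose 6.25-fold, the fatty acid receptor gene Ffar2 rose 5.30-fold and the metallothionein gene Mt2 rose 4.72-fold. Csf1r, the receptor of macrophage colony-stimulating factor, fell by 3.61 log2 (SE 0.56, adjusted p = 0.0206), and Cd48 fell by 1.95 (SE 0.26, adjusted p = 0.0132).

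Other large rises were in the dehydrogenase gene Ldhd (6.38-fold), the olfactory receptor gene Olfr65 (6.28-fold), Mir155hg, the host of a leukocyte microRNA (5.93-fold), the cytoskeletal gene Gas2l1 (5.56-fold) and AA386476 (5.33-fold). Falls included the muscle kinase gene Speg (by 3.14 log2), Erdr1 (by 2.91), the centrosomal gene Lrrcc1 (by 2.64), the DNA glycosylase gene Neil3 (by 2.10), Ccdc57 (by 2.00), Btbd11 (by 1.95), the adaptor gene Ap1s2 (by 1.94) and the mast cell receptor gene Milr1 (by 1.91). Among list members, the erythroid anion exchanger gene Slc4a1 rose 4.78-fold, the imprinted gene Ndn rose 2.32-fold, the adhesion gene Esam fell by 1.12 log2, and the Polycomb genes Cbx2 and Eed fell by 1.16 and 0.97. In total 75 genes rose and 109 fell. Igk, Igkv8-30, Olfr65, Gas2l1 and Slc4a1 lay below the 25th percentile of all genes in young arrays, and Csf1r, Cd48 and Btbd11 in aged arrays, so the size of these changes is uncertain.

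Those calls rested on a scatter shared with the steady-state arrays: limma called 0 genes on the 4 transplanted arrays alone (636 at unadjusted p under 0.05), and 0 with array quality weights (635). Leaving out young transplanted array 1 or 2 gave 1139 or 1467 calls, aged transplanted array 1 or 2 gave 396 or 70, and any 1 steady-state array gave 47 to 62. No overlap between the arrays was seen for 31.7% of all genes, where chance gives 33.3%. For 37 of the 87 called genes with another probe set above the dim filter, at least 1 other probe set pointed the opposite way, among them Ap1s2, Csf1r, Gas2l1, Lrrcc1, Slc4a1 and Speg.

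The 30 genes reported higher with age had a median of 0.90 log2 in transplanted HSC, and 29 of 30 lay above 0. Camera gave an adjusted p of 2.16e-14 (0.00205 with an estimated correlation); 2 rose over all genes, Plscr2 and Mt2, and 16 rose adjusted over the list alone. Vwf (log2 0.94, SE 0.30, adjusted p = 0.178), Selp (0.78, adjusted p = 0.18), Clu (1.45, adjusted p = 0.201) and Cavin2 (1.01, adjusted p = 0.0647) did not pass singly. Cell cycle genes had a median of -0.38, with 0 of 27 called (camera adjusted p = 0.00394; adjusted p = 0.871 with an estimated correlation). The other 19 lists had adjusted p of 0.235 or above.

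The age calls of both settings were set against each other, each on its own arrays but with 1 scatter per gene from the common fit, so a gene with low scatter was called more easily in both. Of the 131 genes that rose in steady-state HSC and the 75 that rose in transplanted HSC, 16 were shared. They included Plscr2, Mt2, the cysteinyl leukotriene receptor gene Cysltr2, the hypoxia factor gene Epas1, Ffar2, the growth factor gene Nrg4, Ramp2 and Tdrd9. Cd48, Cdk5rap1 and Mgst1 fell in both. Nxnl2 alone was called in opposite directions (1.32 and -1.11 log2). The 19 calls shared in direction became 7 to 62 when 1 array was left out and 8 with the replicate number as a block. No call was shared when each effect was fitted by limma on its own arrays, since 0 were then called in transplanted HSC (636 at unadjusted p under 0.05).

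The 200-gene steady-state signature had a signed median of 1.37 log2 in steady-state HSC and 0.38 in transplanted HSC (limma fry adjusted p = 0.000176). That p rests on the scatter shared with the steady-state arrays and may be too small. No transplanted set without an effect was simulated. Of the 200 genes, 21 were also on the list of 30 genes reported higher with age, so the signature and that list are not independent. The other 179 had a signed median of 0.31 log2 in transplanted HSC. In transplanted HSC, 89 of 100 genes that were higher in aged steady-state HSC lay above 0 (median 0.50) and 65 of 100 that were lower lay below 0 (median -0.19). In iPSC the signed median over the 154 measured signature genes was 0.02, with 83 in the steady-state direction (limma fry adjusted p = 0.407). The 100 genes higher in aged HSC had medians of 6.02 and 5.87 log2 in young- and aged-origin iPSC, against 8.33 in aged steady-state HSC. Of them, 27 and 23 lay under the 25th percentile of all genes in these iPSC groups. This dimness limits what the iPSC median could show. The signed median in transplanted HSC stayed above 0 in all alternatives run. In iPSC it turned below 0 in some of them. The limma fry adjusted p in iPSC was 0.0336 with the replicate number as a block, where the median was above 0. It was 0.00875 without young steady-state array 1.

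Averaging the age effect over both settings used 5 aged and 5 young arrays. Plscr2 rose 12.2-fold (SE 0.17 log2, adjusted p = 1e-05), Gpr183 rose 7.47-fold, Tdrd9 rose 7.21-fold and Mt2 rose 6.87-fold. Also up were Neo1, encoding the netrin receptor neogenin (6.28-fold), Osmr (6.05-fold), Wwtr1 (6.03-fold), Tc2n (5.45-fold), Zg16 (5.44-fold) and Tm4sf1 (5.25-fold). Erdr1 fell by 2.35 log2, Plac8 by 1.68, Cd48 by 1.65, the nuclear receptor gene Hnf4a by 1.61, Satb1 by 1.57, Camk1d by 1.56, Rnase6 by 1.52, Rgs7bp by 1.51, Mmp2 by 1.48 and Ap1s2 by 1.35. Of the 110 called genes with another probe set above the dim filter, 27 had at least 1 that pointed the opposite way, Ap1s2 among them. Procr rose 1.67-fold (SE 0.15, adjusted p = 0.0369), and Selp, Nupr1, Cavin2, Vwf and Clu rose by 2.06, 2.27, 1.57, 1.52 and 2.17 log2. Such averages need not hold in each setting. Osmr moved by 4.56 log2 in steady-state and 0.63 in transplanted HSC, and Rgs7bp by -2.81 and -0.21. In young and aged transplanted HSC, Rgs7bp stood at 4.82 and 4.60 log2. That is close above the 25th percentile of all genes there (4.49 and 4.51), so a fall could hardly show. The difference between the settings passed for Osmr and Rgs7bp, and for Wwtr1, Selp and Nupr1.

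In total 151 genes rose and 98 fell. Of the 30 genes reported higher with age, 20 rose (30 adjusted over the list alone; camera adjusted p = 1.73e-49, and 5.39e-05 with an estimated correlation). Cell cycle genes had a median of -0.46 (adjusted p = 7.79e-08; adjusted p = 0.4 with an estimated correlation), and chromatin regulators one of -0.20, with Satb1, Cbx2 and Eed falling (0.0394; adjusted p = 0.26 with an estimated correlation). HSC identity, megakaryocyte and mature blood genes had medians of 0.11, 0.02 and -0.12 at adjusted p = 0.0394 each (adjusted p = 0.55, 0.26 and 0.327 with an estimated correlation); the megakaryocyte median was 0 with each array centred on its median. Array quality weights gave 63 calls, leaving out young transplanted array 1 or 2 gave 932 or 1191, and leaving out any 1 steady-state array gave 89 to 114.

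The age effects of both settings were compared through their difference, transplanted minus steady-state. Osmr had the smallest adjusted p, with a difference of -3.93 log2 (SE 0.32, adjusted p = 0.00298): it rose in steady-state HSC and stood at 3.64 ± 0.20 and 4.27 ± 0.26 log2 (SD, n = 2 each) in young and aged transplanted HSC, below the 25th percentile of all genes there (4.49 and 4.51). The differences of Selp (-2.56, SE 0.33), Wwtr1 (-2.56, SE 0.39) and Nupr1 (-2.28, SE 0.34) also passed, as did that of Igk in the other direction (4.33, SE 0.56). Nupr1 already stood at 9.38 log2 in young transplanted against 6.22 in young steady-state HSC, and at 10.52 against 9.64 in aged HSC. Selp and Wwtr1 instead stood lower in aged transplanted (9.40 and 5.90) than in aged steady-state HSC (11.37 and 10.00). Levels are hard to compare between the settings, since sex and array preparation changed too. The median of all genes was -0.46 log2 in transplanted minus steady-state HSC, and another Wwtr1 probe set pointed the opposite way in that comparison. Of the 5 genes called for the difference of age effects with another probe set above the dim filter, Etl4 and Lrrcc1 had one that pointed the opposite way. In total 5 genes passed with a positive and 12 with a negative difference. The list of genes reported higher with age had a median difference of -1.12 log2 (4 called, 15 adjusted over the list alone; camera adjusted p = 3.5e-19, and 0.000893 with an estimated correlation).

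Megakaryocyte genes had a median difference of -0.23 (adjusted p = 0.0226; adjusted p = 0.162 with an estimated correlation) and interferon genes one of 0.27 (0.0296; adjusted p = 0.912 with an estimated correlation). Limma called 0 genes for this difference with array quality weights (661 at unadjusted p under 0.05). Leaving out young transplanted array 1 or 2 gave 342 or 723 calls, aged transplanted array 1 gave 52, and any 1 steady-state array gave 1 to 6.

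**Figure D2:**
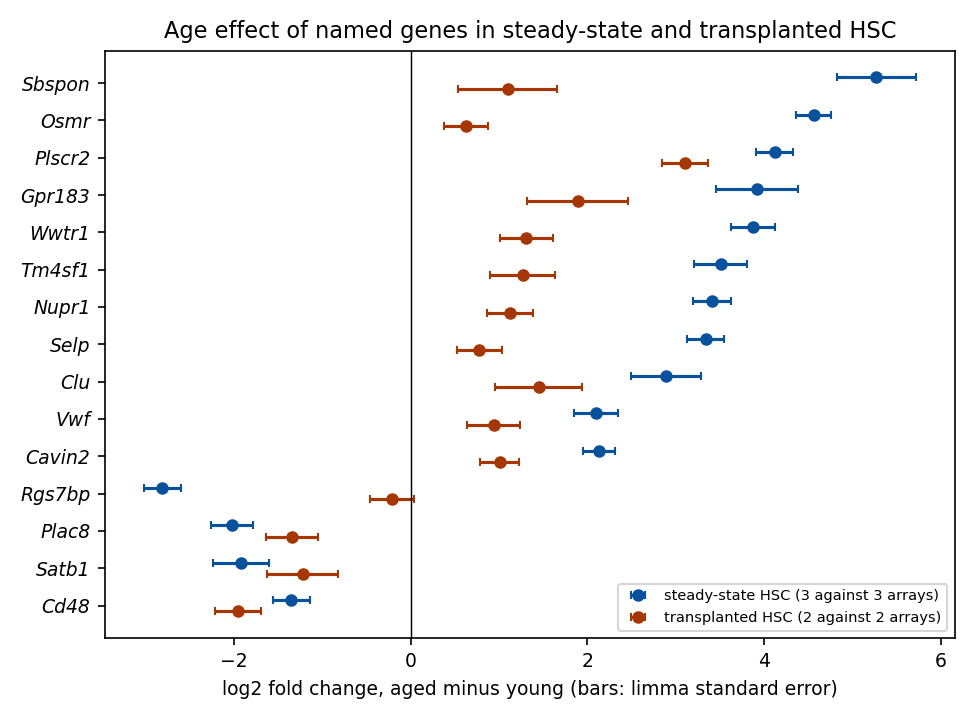
Log2 fold change, aged minus young, of 15 named genes in steady-state HSC (3 against 3 arrays) and in transplanted HSC (2 against 2), with limma standard errors as bars. Osmr moves by 4.56 in steady-state HSC and by 0.63 in transplanted HSC, and Plscr2 by 4.12 and 3.11.

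Transplanted and steady-state HSC were compared over both ages, 4 against 6 arrays. The control probe sets differed between these settings: the beta-actin 5' signal minus its 3' signal was 0.14 ± 0.09 log2 (SD, n = 4) in transplanted HSC and -2.16 ± 0.10 (n = 6) in steady-state HSC, the 18S ribosomal RNA 3' probe set read 14.45 ± 0.07 and 10.40 ± 0.45, and the hybridisation control bioC read 12.42 ± 0.17 and 10.69 ± 0.33. Xist, the RNA of the inactive X chromosome in females, read 13.43 in transplanted and 6.22 in steady-state HSC, and the Y-linked Eif2s3y and Kdm5d read 3.73 and 2.95 against 10.53 and 8.29. The steady-state labels say male. Transplantation, sex and array preparation therefore changed together. The median of all genes was -0.46 log2 as deposited, -0.66 with each array centred on its median and -0.03 after quantile normalisation, so the changes below are relative to -0.46.

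Relative to that shift, the homeobox gene Hoxa3 was higher by 6.68 log2, the haemoglobin gene Hba-a2 by 6.16, the linker histone gene H1f4 by 6.09, Masp2 by 5.89 and the DNA methyltransferase gene Dnmt3a by 5.44. The cell cycle gene E2f5 was at -5.11 relative to the shift, the syntaxin gene Stx6 at -4.93, the X-linked Chm at -4.77, the myeloid genes Chil3 and Ctss at -4.25 each and the signalling inhibitor gene Socs3 at -4.08. Transcription factor genes of HSC were also lower, with Hlf at -2.14 and Tal1 at -1.75, and the surface genes Procr and Kit were at -1.22 and -0.80. Polycomb Rnf2 and Eed were at -3.07 and -1.59 and the deacetylase gene Sirt1 at -2.82. Among these, Hlf, Kit, Rnf2, Dnmt3a and Stx6 had another probe set that pointed the opposite way. All genes named here kept their direction under both other scalings.

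In total 2698 genes were higher and 6836 lower (28.3% higher), against 4391 and 4690 after quantile normalisation (48.4% higher). Of the 4761 called genes with another probe set above the dim filter, 2994 had at least 1 that pointed the opposite way. HSC identity genes had the lowest median among the larger lists after immediate early genes (-0.81 and -0.84 relative to the shift), with 7 of 27 identity genes above the shift. On the deposited scale, without regard to the shift, 2 identity genes were called higher and 21 lower, and the same numbers adjusted over the list alone. Camera gave no list an adjusted p under 0.05 (smallest 0.252), and at unadjusted p the fit as a whole had 9894 genes under 0.05.

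**Figure D3:**
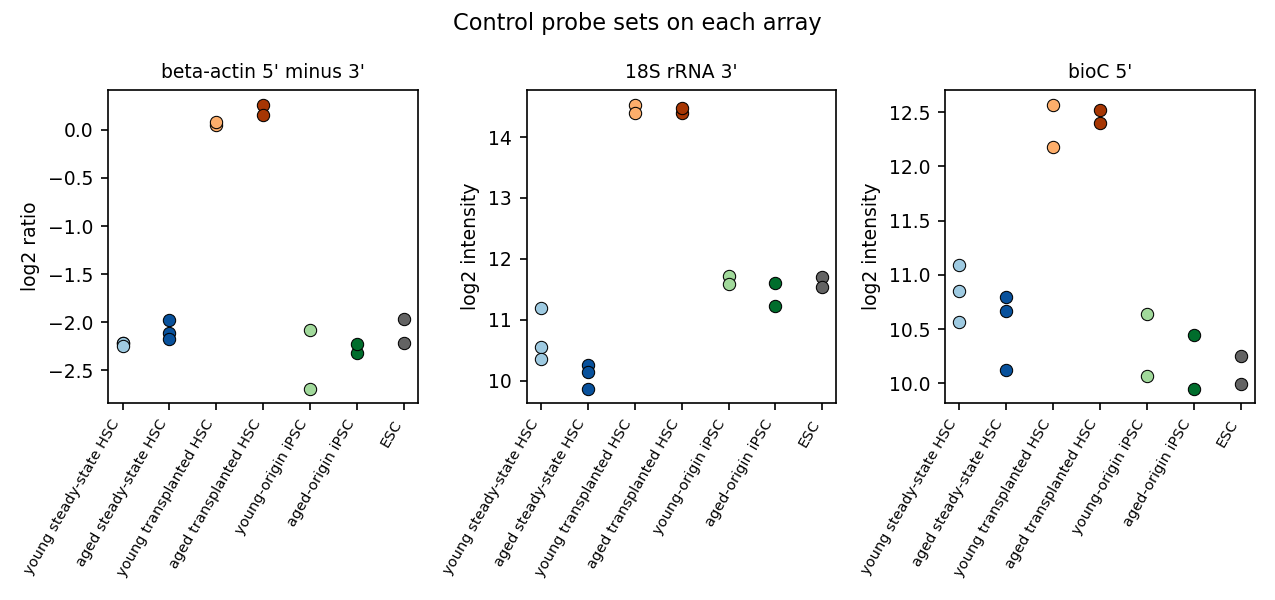
Control probe sets on each array by group: the beta-actin 5' minus 3' log2 ratio, the 18S ribosomal RNA 3' log2 intensity and the bioC hybridisation control log2 intensity, 1 point per array. The 4 transplanted arrays lie above the other 12 in each panel.

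The question whether iPSC kept the age of their origin was addressed with 2 aged-origin against 2 young-origin arrays. The Y-linked translation factor gene Eif2s3y rose 39.8-fold (log2 5.32, SE 0.36, adjusted p = 0.00121), from 3.76 ± 0.20 to 9.07 ± 0.23 log2 (SD, n = 2 each). The young-origin level lay below the 25th percentile of all genes (4.81), so the fold depends on background: the change was 2.71 log2 with the mean of all probe sets and 2.96 with a pseudocount of 64, and stayed called in both. It was the only gene that limma called of 13645, and 679 had an unadjusted p under 0.05. The next smallest p-values were for Gypc (-0.89, SE 0.13, adjusted p = 0.507), Cd300a, Rmdn2 and Spink1, none past the threshold. The HSC age genes Vwf (0.24), Selp (0.17) and Clu (-0.15) and the pluripotency genes Pou5f1 (0.15), Nanog (-0.28) and Sox2 (-0.12) had adjusted p of 0.976 or above.

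Of the 23 measured genes reported higher in aged HSC, 0 were called by limma, 0 passed adjusted over the list alone, and their median was 0.04 log2 (camera adjusted p = 0.536). Proteostasis genes had a median of -0.09 with 0 of 19 called (adjusted p = 0.046; adjusted p = 0.829 with an estimated correlation; median 0 after quantile normalisation), and the sex-linked list stood higher (median 1.10, adjusted p = 6.42e-05; adjusted p = 0.541 with an estimated correlation). Of its 3 measured genes, Eif2s3y was called, and Eif2s3y and the Y-linked Uty (log2 1.10, SE 0.33, adjusted p = 0.976 over all genes) rose adjusted over the list alone, while the X-linked Xist was at -0.09. Leaving out aged-origin array 1 or 2 gave 0 calls each (862 and 678 genes at unadjusted p under 0.05). With an intensity trend and robust prior, Erdr1 (0.80 log2, adjusted p = 0.0443) was called in place of Eif2s3y.

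The age effect of iPSC minus that of steady-state HSC was tested on all 16 arrays. Sbspon (-5.20 log2, SE 0.62), Osmr (-4.30, SE 0.35), Plscr2 (-4.11, SE 0.28), Nupr1 (-3.74, SE 0.30), Wwtr1 (-3.70, SE 0.33), Selp (-3.17, SE 0.33), Clu (-3.05, SE 0.55) and Vwf (-1.86, SE 0.35) differed, as did Rgs7bp (2.59, SE 0.28), Camk1d (2.16, SE 0.40) and Eif2s3y (4.96, SE 0.42), with adjusted p from 1.18e-05 to 0.028. In total 7 genes had a positive and 58 a negative difference, and 4 of the 22 with another probe set above the dim filter had one that pointed the opposite way. Of these 65, 15 lay below the 25th percentile of all genes in both iPSC groups, Sbspon, Osmr and Plscr2 among them. An age effect could hardly show there, so for these genes the difference restates the steady-state effect with its sign turned. Rgs7bp lay close above that percentile, at 5.07 and 4.85 log2 in young- and aged-origin iPSC. Of the 30 genes reported higher with age, 14 had a negative difference (27 adjusted over the list alone; median -2.11, camera adjusted p = 2.65e-82, and 1.51e-07 with an estimated correlation). The median was -2.12 without the 7 that lay below the 25th percentile in both iPSC groups (4.81 and 4.83). Over the whole list, the median level was 5.72 and 5.81 log2 in young- and aged-origin iPSC. In young and aged steady-state HSC it was 7.85 and 9.89. Some of the genes kept thus lay not far above that percentile in iPSC, so leaving out the 7 does not remove this limit. Megakaryocyte genes had a median of -0.31 with 4 called (adjusted p = 1.19e-05, and 0.0059 with an estimated correlation). The sex-linked list had a median of 0.96 (adjusted p = 2.52e-07, and 0.0161 with an estimated correlation), with all 4 measured genes above 0 and Eif2s3y and the Y-linked Kdm5d (1.08, SE 0.29, adjusted p = 0.22 over all genes) rising adjusted over the list alone.

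Cell cycle genes had a median difference of 0.49 (adjusted p = 6.34e-07), interferon genes 0.23 (0.00253), erythroid genes 0.23 (0.0247) and mature blood genes 0.20 (0.0261), with adjusted p = 0.26, 0.26, 0.26 and 0.256 with an estimated correlation. The 10 arrays compared, fitted alone, gave 185 calls, which held all 65. Leaving out 1 iPSC array gave 31 to 35 calls, and leaving out young transplanted array 1 or 2 gave 119 each.

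How far iPSC resembled ESC was asked with 4 against 2 arrays. The maternally expressed long non-coding RNA Meg3 was lower in iPSC by 11.1-fold (log2 -3.47, SE 0.28, adjusted p = 0.00163), at 6.05 ± 0.00 and 6.36 ± 0.53 log2 in young- and aged-origin iPSC against 9.68 ± 0.76 in ESC (SD, n = 2 each). The imprinted genes Mcts2 (log2 -3.44, SE 0.24) and Zdbf2 (4-fold, log2 SE 0.13) were lower too, as were Cyb5r1 (-1.98), Mep1b (-1.48), the lysosomal macrophage gene Cd68 (-1.67), Pla2g4a (-1.11) and Shisa4 (-0.97). Higher in iPSC were the meiotic gene Rec114 (2.52-fold), the X-linked homeobox gene Rhox5 (2.27-fold), the decoy receptor gene Il1r2 (2.21-fold), Gm9112 (1.83-fold), Gm9564 (1.77-fold) and 2610035D17Rik (1.73-fold), of which 2610035D17Rik had another probe set that pointed the opposite way. Eif2s3y was lower in the mean of both iPSC groups (log2 -2.73, SE 0.31), but only through the young-origin lines. It was at 3.76 in young-origin iPSC, 9.07 in aged-origin iPSC and 9.14 in ESC.

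In total 6 genes were higher and 9 lower (40% higher), against 3 and 8 after quantile normalisation (27.3% higher). Pou5f1 (-0.12, SE 0.11), Sox2 (-0.09, SE 0.14), Nanog (-0.45, SE 0.17) and Tfcp2l1 (-0.44, SE 0.13) did not pass. Among 18 imprinted genes, 1 fell (3 adjusted over the list alone), with a median of -0.10 (camera adjusted p = 0.018; adjusted p = 0.389 with an estimated correlation). Fibroblast genes, which mark feeder cells, had a median of -0.19 (adjusted p = 0.00279; adjusted p = 0.389 with an estimated correlation; 0 called by limma, 4 adjusted over the list alone), and Lox and Fn1 did not pass. Interferon genes stood higher (median 0.19, adjusted p = 0.0013), as did megakaryocyte genes (median 0.14, adjusted p = 0.0494), each at adjusted p = 0.389 with an estimated correlation. Immediate early genes, which include Fos and Dusp1, stood lower (median -0.24, adjusted p = 0.00151, and 0.308 with an estimated correlation). The sex-linked list stood lower too (median -1.22, adjusted p = 7.23e-05, and 0.308 with an estimated correlation), with Eif2s3y low in the young-origin lines alone. An intensity trend with a robust prior gave 66 calls, and leaving out aged-origin array 1 or 2 or young-origin array 1 gave 7, 8 or 8.

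**Figure D4:**
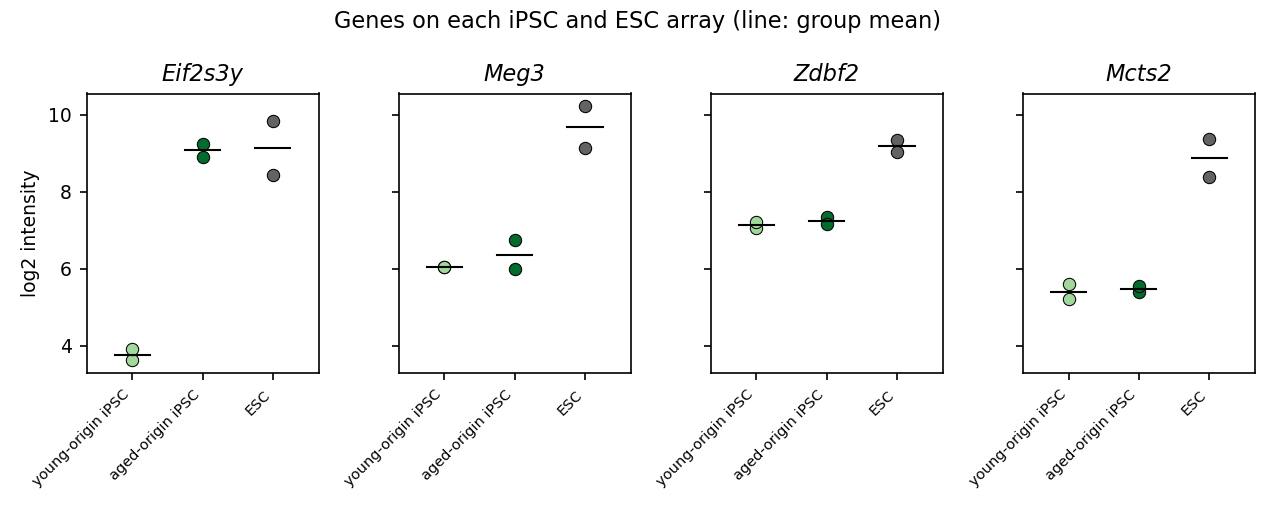
Log2 intensity of Eif2s3y, Meg3, Zdbf2 and Mcts2 on each iPSC and ESC array, 1 point per array with a line at the group mean. Eif2s3y is at 3.76 in young-origin iPSC against 9.07 in aged-origin iPSC, and Meg3, Zdbf2 and Mcts2 are lower in both iPSC groups than in ESC.

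The change from blood stem cell to iPSC was taken over both ages, 4 against 6 arrays. The leukocyte phosphatase gene Ptprc was lower in iPSC (log2 -9.08, SE 0.12, adjusted p = 7.99e-16), the lysozyme gene Lyz1 by 8.68, Myct1 by 8.57, the granule proteoglycan gene Srgn by 8.45, Hoxa9 by 8.32, Meis1 by 8.24, Angpt1 by 8.20, Rgs18 by 8.05, Ctla2b by 7.87 and Cytip by 7.86. The pluripotency factor gene Sox2 rose 365-fold (SE 0.13 log2, adjusted p = 1.33e-15), Dppa2 rose 348-fold and the cadherin gene Cdh1 rose 281-fold, with Dppa5a, Eras, Tdgf1, Tubb2b, Morc1, Rhox5 and Fgf4 between 144- and 242-fold. Pou5f1 rose 82.2-fold and Nanog 77.1-fold, while Kit (-4.88 log2), Procr (-5.32), Slamf1 (-4.33), Vwf (-5.30) and Selp (-4.61) fell.

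In total 5701 genes rose and 4728 fell, with a median of 0.17 log2 over all genes. Of the 4997 called genes with another probe set above the dim filter, 1901 had at least 1 that pointed the opposite way. All 26 measured pluripotency genes rose (median 5.56, camera adjusted p = 5.85e-14), 25 of 26 HSC identity genes fell (median -5.37, 6.51e-13), all 22 megakaryocyte genes fell (median -2.86, 2.08e-09), and of the 30 genes reported higher in aged HSC 23 fell and 6 rose (median -2.38, 7.53e-05); the counts adjusted over the list alone were the same. Those 4 lists kept adjusted p of 0.0111 or below with an estimated correlation. Cell cycle genes (23 of 27 rose, adjusted p = 0.000146), fibroblast genes (10 of 14 rose, 0.00237), oxidative phosphorylation genes (21 of 28 rose, 0.000569), interferon genes (15 of 19 fell, 1.33e-05) and myeloid genes (11 of 16 fell, 0.00252) had adjusted p = 0.402, 0.0837, 0.298, 0.0959 and 0.261 with an estimated correlation. The fibroblast genes Ccn2, Sparc and Timp1 rose 44.6-, 34.5- and 19.3-fold in iPSC, which were grown on fibroblast feeders. The collagen gene Col1a1 stayed dim, at 5.51 and 4.96 log2 in young- and aged-origin iPSC against 4.95 and 4.64 in young and aged steady-state HSC. Whether feeder cells gave these signals was not tested. Folds against a gene at background are bounded by that background.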

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

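The tests of array preparation, of sex as the whole cause, of transplantation itself and of an absent Y chromosome were chosen after the values had been seen; the others were planned.

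The control probe sets carried signals outside the main measurement. The difference of transplanted minus steady-state arrays was 4.05 log2 for the 18S ribosomal RNA 3' probe set, 1.73 for bioC, 1.70 for bioD, 2.29 for the beta-actin 5' minus 3' ratio and 1.01 for that of Gapdh. Transplanted arrays differed from steady-state arrays at 9534 genes. Of the 100 splits of these arrays within each age, the real one alone gave as many and the highest other gave 2. Chance is thus unlikely for this count. Sex of the animals cannot be told apart from the setting, because all arrays of a setting shared the same sex-linked pattern; 3.45% of the called and 3.09% of the tested genes lay on X or Y, and the called share could not have passed 4.42%, so it decides nothing. Different labelling or amplification may account for part of the difference, since all 4 transplanted arrays lay outside the range of the other 12 for 6 of 6 control measures. Transplantation itself cannot be told apart from it, because 0 transplanted arrays had the control profile of the steady-state arrays.

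The age effect differed between transplanted and steady-state HSC at 17 genes by limma's test of the difference. That test called 0 genes with array quality weights and 0 with the replicate number as a block (661 and 1167 at unadjusted p under 0.05). Of the 15 named genes, 0 kept the threshold in all alternatives with every array kept. The named differences, transplanted minus steady-state, were 4.33 log2 for Igk, 3.94 for 6030498E09Rik, 2.60 for Rgs7bp, 2.32 for Olfr65 and 1.71 for Tmem254a. Those below 0 were -3.93 for Osmr, -3.59 for Ccbe1, -2.70 for Lrrcc1, -2.56 each for Wwtr1 and Selp, -2.44 for Nxnl2, -2.28 for Nupr1, -2.19 for Gpld1, -2.14 for Etl4 and -2.11 for Ccdc57. Osmr lay below the 25th percentile of all genes in both transplanted groups, and Etl4 and Lrrcc1 had another probe set that pointed the opposite way. Igk, 6030498E09Rik and Olfr65 lay below that percentile in young transplanted HSC, and Ccbe1, Nxnl2 and Etl4 in aged transplanted HSC. Rgs7bp lay close above it in both, at 4.82 and 4.60 log2 in young and aged transplanted HSC. The size of their differences is uncertain.

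The steady-state age signature was smaller in transplanted HSC, at 0.38 against 1.37 log2. Selection of its genes on the steady-state arrays is argued against as the cause: with signatures formed on the other 4 steady-state arrays, all 9 held-out pairs had a median above that of transplanted HSC, from 1.09 to 1.35. For a compressed scale over all signature genes, the spread of transplanted minus iPSC was set over that of steady-state minus iPSC. It was 1.03 (bootstrap interval 0.96 to 1.11), where the ratio of the age effects was 0.28. This test cannot decide, because the preparation and scatter of the transplanted arrays may add spread of their own. Compression of single genes near background is open too. Under the 25th percentile lay 20 of the 100 genes higher in aged HSC in young transplanted HSC, against 12 in young steady-state HSC. A smaller age difference after transplantation, and the sex and preparation of those arrays, stay open and were not separated by any test.

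The age effect differed between iPSC and steady-state HSC at 65 genes by limma's test of the difference. Differences, iPSC minus steady-state, were -5.20 log2 for Sbspon, -4.30 for Osmr, -4.11 for Plscr2, -3.74 for Nupr1, -3.70 for Wwtr1, -3.17 for Selp, -3.05 for Clu and -1.86 for Vwf, and 4.96 for Eif2s3y, 2.59 for Rgs7bp and 2.16 for Camk1d. Sbspon, Osmr and Plscr2 are among 15 of the 65 genes below the 25th percentile of all genes in both iPSC groups, where an age effect could hardly show and the difference restates the steady-state one. Rgs7bp lay close above that percentile, at 5.07 and 4.85 log2 in young- and aged-origin iPSC.

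Aged-origin and young-origin iPSC differed at the Y-linked Eif2s3y. Another active X chromosome in the young-origin lines is argued against, since X-linked genes lay -0.042 log2 from the autosomal median (bootstrap interval -0.061 to -0.026). Absence of a Y chromosome from the young-origin lines cannot be told apart from silencing of Eif2s3y, because 0 other Y-linked genes were above the 50th percentile in aged-origin arrays. The dimmer Uty and Kdm5d went the same way as Eif2s3y, at 5.60 ± 0.29 and 4.22 ± 0.01 log2 in aged-origin against 4.49 ± 0.42 and 3.08 ± 0.21 in young-origin lines (SD, n = 2 each). Usp9y (4.40 and 4.57) and Sry (5.86 and 5.94) went the other way by less, and Orly (5.55 and 5.49), Tspy-ps (4.83 and 4.68), Uba1y (4.73 and 4.61) and Zfy2 (4.45 and 4.28) were slightly higher in aged-origin lines. Uty and Kdm5d lay below the 25th percentile (4.81) in young-origin lines, which an absent Y chromosome would also give. Silencing of Eif2s3y alone would not lower them. Kdm5d lay below that percentile in aged-origin lines too (4.83) and was too dim to decide. Uty lay above it there, but its difference did not pass (log2 1.10, limma adjusted p = 0.976), so it does not decide either. Whether origin age or the sex of the donors set the difference cannot be read from 2 arrays per group.

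For the steady-state age effect, the real split gave 161 genes and the highest of the others 0; the 10 splits of these arrays are too few for a share under 0.05. The averaged age effect gave 249 genes against 146 for the highest of the other 59 of 60 splits. The real split was 1.67% of them, so chance is unlikely for this count but not excluded. For iPSC minus steady-state HSC, 10429 genes stood against 9 for the highest other of 100 splits, so chance is unlikely there too.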

How the results depend on the processing

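Chosen after seeing the data were the fits on 6 or 4 arrays, the array weights, the removal of X and Y genes, the crossed pairing and the count of shared calls. In the values below the cause was not tested, except that a stricter filter or fewer arrays leave less to call.

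With genes below the 50th percentile left out, the calls were 89 for the steady-state age effect, 112 for the transplanted one, 145 for their average, 3 for their difference, 33 for iPSC minus ESC and 29 for the difference of iPSC and steady-state age effects. All 16 arrays in one fit gave 280, 674, 695 and 199 for the 4 HSC age contrasts, 9 for iPSC minus ESC and 51 shared age calls. The 6 steady-state arrays alone gave 415, the 4 transplanted arrays alone 0 and the 10 arrays of iPSC and steady-state HSC 185; shared calls were then 0. Array weights gave 613, 0, 63 and 0 for the HSC age contrasts and 0 shared calls. A required 2-fold change left 122 averaged age calls, 5634 for transplanted minus steady-state HSC and 5810 for iPSC minus steady-state HSC. A pseudocount of 64 gave 30 for iPSC minus ESC and 112 for the difference of iPSC and steady-state age effects; the trend prior gave 66 for iPSC minus ESC. Without X and Y genes limma called 0 in iPSC by origin (647 at unadjusted p under 0.05). Camera kept 12 of 43 list calls with an estimated correlation.

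The replicate numbers did not pair the arrays: same-numbered steady-state pairs had deviations correlated at 0.145, -0.202 and 0.193. As a replicate block they gave 94, 28, 97 and 0 calls for the HSC age contrasts (1167 genes at unadjusted p under 0.05 for the last), 2 for iPSC origin, 19 for the difference of iPSC and steady-state age effects, 8 shared calls and a signature median of 0.0328 in iPSC (limma fry adjusted p = 0.0336). Crossed numbers in transplanted HSC, whose same-numbered pairs correlated at -0.158, gave 66 calls.

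The iPSC signature median, 0.0192, was -0.0025 with the called genes as the signature and -0.002 after quantile normalisation, and -0.0002 with a pseudocount of 64, at limma fry adjusted p of 0.675 or above each. With a pseudocount of 64, Lrrcc1 turned to 0.17 in transplanted HSC and 0.16 in the difference of age effects. With the mean of all probe sets, transplanted minus steady-state turned to 0.30 for Mllt3, 0.37 for Slamf1, -0.22 for Mcm6 and 0.23 for Ighm.

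Leaving out 1 array at a time, where a lone array is assumed to vary like the other groups, gave 78 to 257 steady-state, 47 to 1467 transplanted, 89 to 1191 averaged and 1 to 723 difference calls, 9003 to 9976 for transplanted minus steady-state, 0 to 1 for iPSC origin, 7 to 16 for iPSC minus ESC, 9550 to 11052 for iPSC minus steady-state, 31 to 119 for the iPSC difference, 7 to 62 shared calls and 35 to 47 list calls. The highest of the HSC age counts and of the shared calls came without young transplanted array 2. The signature median ranged from 0.341 to 0.424 in transplanted HSC and from -0.0001 to 0.0499 in iPSC, where it turned below 0 without young-origin array 2 and had a limma fry adjusted p = 0.00875 without young steady-state array 1. Of the named genes past the threshold, 19 of 28 kept it without any 1 array for the steady-state age effect, 9 of 26 for the transplanted one, 21 of 30 for the average, 1 of 15 for the difference, 36 of 36 for transplanted minus steady-state, 0 of 1 for iPSC origin, 6 of 15 for iPSC minus ESC, 42 of 42 for iPSC minus steady-state and 8 of 11 for the iPSC difference. In all the other alternatives, with every array kept, these numbers were 20, 0, 20, 0, 30, 0, 5, 42 and 8. Levels near array background limit the folds of genes dim in one group.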

Other observations

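The genes here were chosen after their values had been seen, and no explanation was tested. In the Dlk1-Dio3 imprinted region, the non-coding Rian and Mirg were read beside Meg3. Rian was at 3.82 ± 0.18 and 4.24 ± 0.04 log2 in young- and aged-origin iPSC and 5.68 ± 0.05 in ESC, and Mirg at 5.36 ± 0.30, 5.39 ± 0.57 and 6.02 ± 0.14 (SD, n = 2 each). Rian lay below the 25th percentile of all genes in both iPSC groups (4.81 and 4.83) and was too dim for the limma test, and Mirg did not pass (log2 -0.65, limma adjusted p = 0.287). The protein-coding Dlk1 was at 5.65 ± 0.23 and 5.56 ± 0.20 in iPSC and 5.54 ± 0.12 in ESC. In HSC, Meg3 stood at 9.42 ± 0.80 in young and 9.79 ± 0.62 in aged steady-state arrays (n = 3 each) and at 4.93 ± 0.03 and 6.02 ± 1.42 in transplanted arrays (n = 2 each).

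Other B lineage genes were read beside the immunoglobulin rise in aged transplanted HSC. Igk was at 8.75 ± 0.92 log2 in aged and 4.18 ± 0.35 in young transplanted HSC and Jchain at 5.55 ± 0.11 and 3.48 ± 0.00, Cd79a was at 4.53 ± 0.03 and 4.35 ± 0.32, Ms4a1 at 3.86 ± 0.06 and 3.74 ± 0.36 and Ighm at 4.21 ± 0.48 and 4.44 ± 0.12 (SD, n = 2 each). The 25th percentile of all genes was 4.51 in aged and 4.49 in young transplanted HSC. Cd79a, Ms4a1 and Ighm lay below or close to it, too dim to show whether they moved. Igk and Jchain lay below it in young transplanted HSC, so the size of their differences is uncertain. Cd79b lay above it in both groups, at 6.5 ± 0.07 in aged and 7.08 ± 0.32 in young transplanted HSC. It was thus lower in aged HSC, but did not pass (log2 -0.58, limma adjusted p = 0.299). In aged steady-state HSC, Jchain was at 5.20 ± 2.56 (n = 3).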
